A study of Mus musculus with 12 samples.

How the data were processed

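Gene expression was measured in macrophages sorted for high CD11b from mouse tumours of 2 kinds, PyMT breast tumours and MCA fibrosarcomas, each from wild-type and S1PR1 knockout mice. Per the labels, RNA came from pooled sorted cells and was isolated with the RNeasy micro kit. It was checked on a Bioanalyzer and amplified. The labels name 2 amplification systems, the µMACS SuperAmp kit and the NuGEN Ovation Pico kit followed by biotin labelling, and do not say whether both were applied to every sample. The 12 single-colour Illumina BeadChip arrays sit on 2 BeadChips. Each of the 4 groups of genotype and tumour has 2 arrays. Of the other 4 arrays, 1 is a mixed control of PyMT macrophages, 2 are mixed controls of MCA macrophages, and 1 repeats the sample of KO_MCA replicate 1 on the other BeadChip. What was mixed in the mixed controls is not given in the sources used here.

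The deposited intensity per probe is the mean bead signal on a linear scale, per the file headers, and is neither normalized nor background-subtracted. The deposited p-value per probe and array tests the signal against background, per the file headers. Which test gave it is not given in the sources used here, and it is not a rank among negative control probes, since it runs far below what such a rank allows. The authors also deposited normalized linear intensity values. Their normalization method is not given in the sources used here, and set against the unprocessed signal of the same array they are a smooth, near monotone transform of it, with Spearman's rho across probes of 0.9998 to 1.000. Their medians per array lie between 88.7 and 90.0, they are not centred, and no direction is unknown because each value belongs to 1 array. All log2 values reported here were computed from the deposited intensity and are not the authors' own.

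Background correction and normalization used neqc of limma 3.58.1 in R 4.3.3, with tables read by data.table (version 1.17.8). This step infers the background of each array from the signal and the deposited p-value, adds an offset of 16, quantile normalizes and takes log2. All 12 arrays were normalized together. The inferred background mean was 80.3 to 89.9 per array with an SD of 2.02 to 2.59. neqc was the design fixed in advance and was kept although the deposited p-value is not a rank, with normexp at an offset of 50 and without the p-value as an alternative. Of 46237 probes, 35784 had 1 gene symbol in the platform table, 0 had several and 10453 were not listed there. A RefSeq gene table of GRCm38.p6 updated the symbols of 937 probes, and 4527 kept the platform symbol for want of a match. Probes with a deposited p under 0.05 on at least 2 of the 8 group arrays were kept, which left 26748 probes, 21699 of them with a symbol. For each gene the probe with the highest mean signal was used, giving 14103 genes, 4880 of which had more than 1 such probe. A gene counts as below background on an array where that probe had a deposited p of 0.05 or more.

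A limma model with 4 groups (residual df 4, prior df 2.75) tested knockout against wild type in each tumour and the difference of these effects. An additive model of genotype and tumour (residual df 5, prior df 2.92) tested genotype over both tumours and PyMT against MCA. P-values were two-sided and adjusted over all 14103 genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Where a gene was below background on every array of 1 group, only a lower bound of the fold is given, taken against the lowest normalized signal among probes above background on each array of that group or the gene's own signal, whichever was higher. Group values are means of log2 intensity with SD, and contrasts carry their standard error (SE). The labels do not say whether replicates came from separate animals or pools, so p-values measure only the spread between these arrays, which may be technical, and the small number of arrays limits the precision.

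The 25 gene lists, written before the data were examined together with the groups, tests, most alternatives and naming rule, were these. Functional lists covered S1P receptors and metabolism, the NLRP3 inflammasome and IL-1 family, angiogenic and lymphangiogenic factors, classical and alternative macrophage activation, macrophage identity, antigen presentation, interferon-stimulated genes, chemokines and receptors, cell cycle, hypoxia and glycolysis, lipid and cholesterol metabolism, immediate early and heat shock genes, ribosomal proteins and oxidative phosphorylation. Marker lists covered monocytes, neutrophils, mast cells with basophils and eosinophils, dendritic cells, T and NK cells, B and plasma cells, epithelial and mammary cells, fibroblasts and sarcoma, endothelium and sex genes. Each list with at least 3 measured genes was tested with camera at a preset correlation between genes of 0.01 and adjusted over the 25 lists. Camera with an estimated correlation and fry accompanied it. With an estimated correlation camera called 0 lists in each comparison. Fry asks only whether a list's genes move one way on balance. It called 0 lists for each knockout comparison, 1 for the difference between tumours and 6 for PyMT against MCA. Members below background in 1 group were also set to their bounds. The medians of the 21 called lists of the knockout and tumour comparisons then moved by -0.03 to 0 on the log2 scale and 0 changed sign.

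Genes were named by rule. S1pr1, Nlrp3 and Il1b were always named. For each knockout comparison the rule took up to 10 genes per direction with the smallest p among called genes, filled to 5 per direction by unadjusted p where fewer passed. For the difference between tumours it took the 5 smallest p. For PyMT against MCA it took the 10 largest changes per direction among called genes. In each described list it took up to 4 members with the smallest p. Names that are only clone, locus or predicted-gene names were counted and not named. Other probes of a named gene were checked. Alternatives were other background corrections, scalings, filters, probe rules, variance models, sample sets and leaving out each array in turn.

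The pipeline was tested on simulated arrays of 14103 genes with the spread of each gene measured per tumour. Knockout and wild-type arrays of a tumour were given the same spread, unlike the measured replicates. For PyMT, log2 changes of 1, 2 and 3 were called for 29.9%, 91.0% and 95.5% of changed genes, and 82 unchanged genes were called too. For MCA the shares were 13.4%, 97.0% and 98.5%, with 3 unchanged genes called. Over both tumours they were 65.7%, 97.0% and 100%, with 2 unchanged genes called. For the difference between tumours they were 0%, 49.3% and 87.9%, with 8 unchanged genes called. For PyMT against MCA they were 58.2%, 97.0% and 100%, with 13 unchanged genes called. In each comparison camera called 10 of 10 simulated lists of 30 genes shifted by 0.5 and 0 of 10 unshifted lists, except 1 of 10 in MCA. The simulated genes varied independently of each other. These counts therefore do not show how often camera calls unshifted lists whose genes move together.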

Results

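Genome-wide expression was measured in tumour-associated macrophages that carried or lacked S1PR1, a receptor for the lipid mediator sphingosine-1-phosphate. The macrophages were sorted for high CD11b from PyMT breast tumours of female mice and MCA fibrosarcomas of male mice, all labelled C57BL/6. Each group, KO_PyMT, WT_PyMT, KO_MCA and WT_MCA, had 2 arrays of pooled cells. Tumour type therefore goes with sex, and also with BeadChip, since all PyMT group arrays were on 1 BeadChip and all MCA group arrays on the other. The genotypes of a tumour shared a BeadChip. Whether the amplification system also went with tumour is not given in the sources used here. The median raw signal per array was 83 to 92.5, and 18316 to 23223 probes (39.6% to 50.2%) were above background.

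S1pr1 itself could not be checked. Its only probe was above background on 0 of 12 arrays, with signals of 76.0 to 88.2 and a lowest detection p of 0.467, so the arrays neither bear out nor contradict the genotype labels. Xist, the RNA of the inactive X chromosome, went with the labelled sex, at 8.93 to 9.27 on the log2 scale on PyMT arrays and 4.06 to 4.26 on MCA arrays, and so did the Y-linked Eif2s3y, at 4.15 to 4.51 and 5.29 to 6.58. The Y-linked Kdm5d did not separate the sexes, at 4.14 to 4.37 and 4.18 to 4.97, and the Y-linked Uty was 4.59 to 4.93 on PyMT arrays and 5.09 to 5.66 on MCA arrays. Replicates differed in quality with both tumour and genotype. Genes above background numbered 9894 to 10247 on KO_PyMT arrays, 10538 to 11030 on WT_PyMT arrays and 11382 to 11809 on MCA group arrays. Between replicates the SD of the log2 difference was 0.762 in KO_PyMT, 0.586 in WT_PyMT, 0.372 in KO_MCA and 0.479 in WT_MCA, with 2206, 1280, 243 and 566 genes more than a factor of 2 apart. The repeat array of KO_MCA replicate 1 differed from its partner with an SD of 0.282.

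In both tumours the knockout arrays had less Nlrp3, the sensor of the inflammasome that activates interleukin-1β. Over both tumours Nlrp3 was 9.18 in knockout and 9.89 in wild-type macrophages, a log2 change of -0.71 ± 0.14 (SE, 4 arrays per genotype, 1.63-fold), and every knockout array lay below every wild-type array. The change was -0.81 ± 0.19 in PyMT, from 9.80 ± 0.15 (SD, n = 2) to 8.99 ± 0.10, and -0.60 ± 0.19 in MCA, from 9.98 ± 0.18 to 9.38 ± 0.05. A further Nlrp3 probe gave -0.66 in PyMT and -0.60 in MCA. Adjusted over all genes the limma p for Nlrp3 was 0.222 in PyMT, 1 in MCA and 0.93 over both, so it did not pass the test across the genome, while it passed when adjusted over the list alone in PyMT and over both tumours. Il1b, the gene for interleukin-1β, differed less, with -0.13 ± 0.18 in PyMT, -0.30 ± 0.18 in MCA and -0.21 ± 0.13 over both tumours (limma adjusted p = 0.93). The effects did not differ detectably between tumours, by -0.21 ± 0.27 for Nlrp3 (limma adjusted p = 0.956) and 0.17 ± 0.25 for Il1b (limma adjusted p = 0.966).

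**Figure D1:**
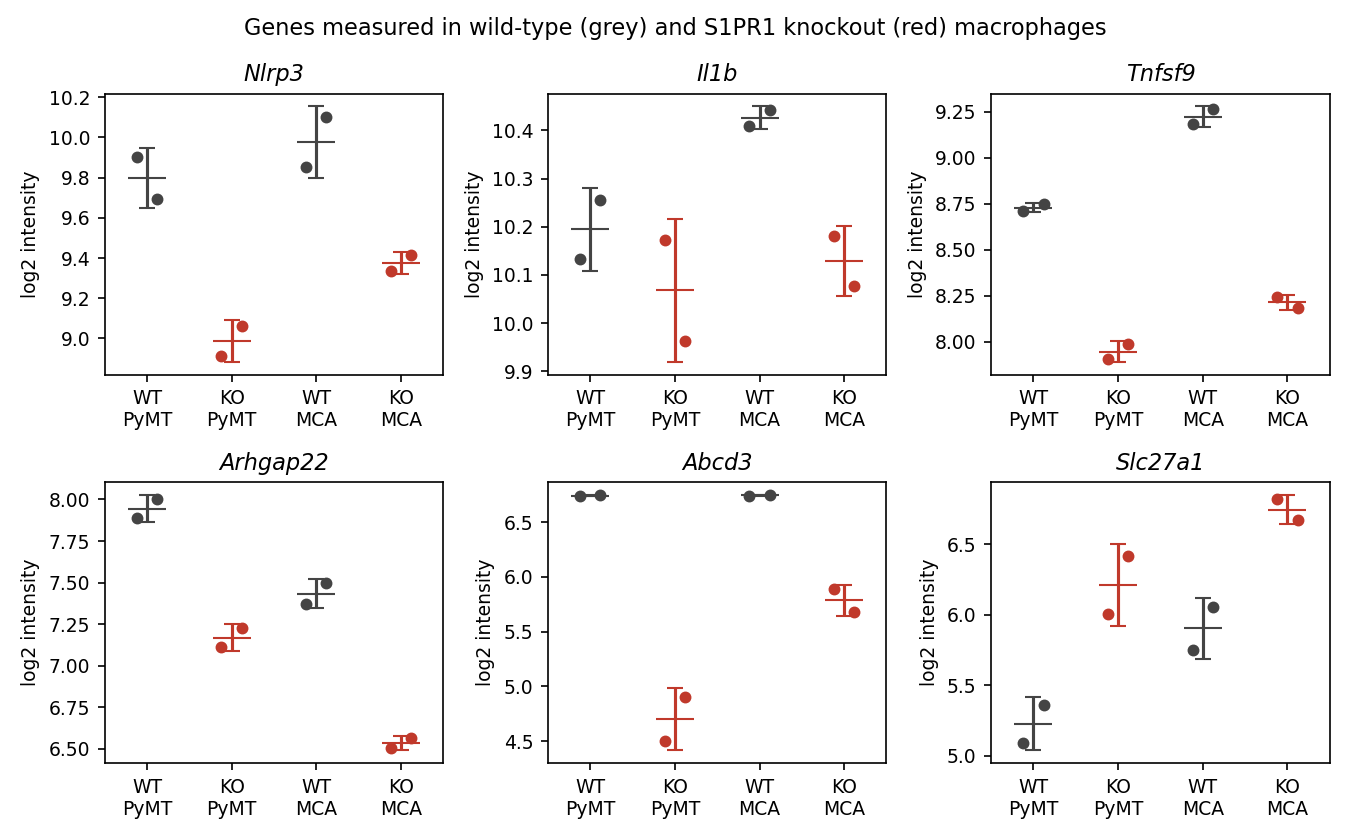
Log2 intensity of 6 genes on each array of the 4 groups (points), with mean and SD (lines), wild type in grey and S1PR1 knockout in red. Nlrp3, Tnfsf9, Arhgap22 and Abcd3 were lower on every knockout array than on every wild-type array, while Il1b and Slc27a1 overlapped between genotypes. Tnfsf9, Arhgap22, Abcd3 and Slc27a1 were chosen by their p on these same arrays, so their separation is not independent support.

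Over both tumours, the genes with the smallest p among those lower in knockout were Tnfsf9, Arhgap22 and Abcd3. Tnfsf9, the ligand of the T cell co-stimulator 4-1BB, was 8.08 against 8.98 (-0.89 ± 0.12, 1.86-fold). Arhgap22 was 6.85 against 7.69 (-0.84 ± 0.12, 1.79-fold). Abcd3, a peroxisomal fatty acid transporter, was 5.24 against 6.74 (-1.50 ± 0.24, 2.83-fold) on its brightest probe, but its next probe gave -0.14. Slc35c2, a nucleotide sugar transporter, and the annexin Anxa3 measured -0.95 ± 0.17 and -1.08 ± 0.20. Higher in knockout were Slc27a1, a fatty acid transporter (0.91 ± 0.16, 6.48 against 5.56), Gdpd3 (1.91 ± 0.38), the myelin protein gene Pmp22 (1.24 ± 0.26, 3 of 4 wild-type arrays above background), the apoptosis inhibitor Api5 (0.74 ± 0.16) and the glutathione transferase Gstt3 (1.14 ± 0.25, 2 of 4 wild-type arrays above background). None of these passed the test. limma called 0 of 14103 genes, with adjusted p of 0.920 to 0.93 for those named, and 722 genes had an unadjusted p under 0.05 (348 higher, 374 lower) where chance gives 705. Testing all 26748 probes also called 0. Without background correction, or from the authors' normalized values, Tnfsf9 and Arhgap22 had limma adjusted p of 0.0447 and 0.0345, at changes of -0.75 and -0.57, or -0.76 and -0.56.

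Of the 25 lists, camera called 4 over both tumours. Interferon-stimulated genes, the antiviral program downstream of interferon receptors, fell, with 25 of 30 measured members lower and 5 higher (median -0.23, camera adjusted p = 2.99e-04, adjusted p = 0.955 with an estimated correlation). Examples were Isg15 (-0.66 ± 0.25), Dhx58 (-0.56 ± 0.20), Ifi35 (-0.71 ± 0.28, 3 of 4 knockout arrays above background) and Isg20 (-0.62 ± 0.22, 2 of 4 knockout arrays above background), and 0 members passed when adjusted over the list alone. Without WT_MCA replicate 1 the median was -0.18 and the call ended (camera adjusted p = 0.283), and without WT_MCA replicate 2 it was -0.38. The NLRP3 inflammasome and IL-1 family fell, with 17 of 20 members lower (median -0.14, camera adjusted p = 0.0175, adjusted p = 0.542 with an estimated correlation). Only Nlrp3 passed when adjusted over the list alone. The channel gene Panx1, the decoy receptor gene Il1r2 and the ATP receptor gene P2rx7 measured -0.83 ± 0.24, -0.55 ± 0.22 and -0.70 ± 0.34, with Panx1 above background on 3 of 4 knockout arrays. This call ended without WT_PyMT replicate 1 (-0.04, camera adjusted p = 0.0654) and without KO_MCA replicate 2 (-0.15, 0.0865) and among genes above background on all 8 arrays (-0.17, 0.0624), and the median was -0.25 without KO_PyMT replicate 1 and -0.07 without WT_MCA replicate 1. Without background correction it was -0.07, and for interferon-stimulated genes -0.14, both still called.

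Alternative activation genes, linked to tissue repair, rose, with 14 of 21 members higher (median 0.34, camera adjusted p = 0.0437, adjusted p = 0.955 with an estimated correlation). The list was called in neither tumour alone, with medians of 0.18 in PyMT and 0.03 in MCA (camera adjusted p = 0.0688 and 0.264). Among the members were the folate receptor Folr2 (1.35 ± 0.40), Retnla (1.14 ± 0.46, 2 of 4 arrays above background in each genotype), the transcription factor Irf4 (0.70 ± 0.33) and the chemokine Ccl24 (0.42 ± 0.22), the last pair above background on 3 of 4 knockout and 2 of 4 wild-type arrays, and 0 passed when adjusted over the list alone. In MCA alone Folr2 measured 0.45 ± 0.35, Irf4 and Ccl24 were above background on 2 and 1 of 4 arrays and Retnla on 0, so these values come mainly from PyMT. Cell cycle genes rose, with 24 of 34 higher (median 0.13, camera adjusted p = 0.0484, adjusted p = 0.955 with an estimated correlation) and 0 passing when adjusted over the list alone. Birc5, the mitotic kinase gene Aurka, the replication licensing gene Cdt1 and the spindle gene Tpx2 measured 1.27 ± 0.33, 1.31 ± 0.47, 0.56 ± 0.15 and 0.43 ± 0.19, with Aurka above background on 3 of 4 wild-type arrays. Both calls lay near the threshold and ended when any of several arrays was left out, even where the cell cycle median rose. That of alternative activation ended without KO_PyMT replicate 2 (0.11), WT_PyMT replicate 1 (0.18), WT_PyMT replicate 2 (0.29), KO_MCA replicate 2 (0.25) or WT_MCA replicate 1 (0.16), with camera adjusted p of 0.0590 to 0.462. That of the cell cycle ended without KO_PyMT replicate 2 (0.04), WT_PyMT replicate 2 (0.06), KO_MCA replicate 1 (0.08), KO_MCA replicate 2 (0.17) or WT_MCA replicate 2 (0.10), with camera adjusted p of 0.0865 to 0.774, and its median was 0.21 without WT_PyMT replicate 1. The processing mattered too. Alternative activation was no longer called without background correction (0.14), from the authors' normalized values (0.14), without a detection filter (0.14), with normexp without the deposited p (0.18) or among genes above background on all 8 arrays (0.34), with camera adjusted p of 0.0703 to 0.337. The cell cycle was no longer called under median scaling (0.13), without a detection filter (0.09), by the mean of probes (0.03) or among genes above background on all 8 arrays (0.12), with camera adjusted p of 0.0509 to 0.255.

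In PyMT tumours the largest differences by p were in genes near background in 1 genotype. R3hcc1l was 6.69 ± 0.17 (SD, n = 2) in knockout and 4.54 ± 0.02 in wild type (4.46-fold). Abcb8, a mitochondrial transporter, was 7.16 ± 0.12 against 4.54 ± 0.34 (6.15-fold, 1 of 2 wild-type arrays above background), although its other probes gave 0.10 and -0.13. Adamtsl5, a matrix protein gene, was 7.15 ± 0.13 against 4.64 ± 0.44. The protease inhibitor Serpinb6 and the thioredoxin-like gene Txnl2 were below background on both wild-type arrays and at least 5.19-fold and 2.97-fold higher in knockout. Lower in knockout were Bet1l, a Golgi SNARE (11.2-fold, 1 of 2 knockout arrays above background), Abcd3 (4.70 ± 0.29 against 6.74), Snn (-2.64 ± 0.30, another probe 0.18) and the deadenylase subunit Cnot10 (-1.64 ± 0.19), the last pair with 1 of 2 knockout arrays above background. H2-Ea, a class II histocompatibility gene that C57BL/6 mice do not transcribe because of a promoter deletion, was 6.03 ± 0.09 on WT_PyMT arrays and below background in KO_PyMT, at least 3.28-fold lower. That signal goes against either the C57BL/6 label of WT_PyMT or the probe as a measure of H2-Ea, and which was not tested. None of these genes passed the test in PyMT. Without background correction the folds shrank and limma called R3hcc1l (0.89), Abcb8 (1.19), Adamtsl5 (1.15), Abcd3 (-0.88) and Snn (-1.17) at an adjusted p of 0.0400, while Bet1l (-1.73) and Cnot10 (-0.62) stayed uncalled. Without a detection filter R3hcc1l, Txnl2 and H2-Ea were called, and with mixed arrays added Abcb8, Txnl2, Adamtsl5, H2-Ea, Abcd3 and Bet1l. By the mean of probes Abcb8 was 0.87 and Abcd3 -0.50, uncalled.

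limma called 0 of 14103 genes in PyMT, with a smallest adjusted p of 0.0707 and 19 genes under 0.1. The simulated arrays had 1210 unchanged genes with an unadjusted p under 0.05. Measured were 1531 such genes (674 higher, 857 lower), and all filtered probes together gave 0 calls. The count was 941 with only the PyMT arrays, 986 with array weights and 997 with the spread of each tumour on its own. The number of calls turned on the knockout arrays, with 108 genes without KO_PyMT replicate 1 and 33 without KO_PyMT replicate 2, where the remaining array is assumed to vary like the other groups. Of the 10 genes named here, 9 and 3 were then among the calls.

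Interferon-stimulated genes fell in PyMT, with 24 of 30 members lower and 6 higher (median -0.43, camera adjusted p = 0.0110, adjusted p = 0.884 with an estimated correlation). Irf7, a driver of type I interferon production, measured -1.51 ± 0.43 (1 of 2 knockout arrays above background) and Oasl1 -0.97 ± 0.32, and Isg20 was at least 1.89-fold lower, with 0 members passing when adjusted over the list alone. The call ended without KO_PyMT replicate 2 (-0.34, camera adjusted p = 0.226), without WT_PyMT replicate 2 (-0.34, 0.163) and among genes above background on all 8 arrays (-0.42, 0.133). The median was -0.23 without background correction and -0.24 from the authors' normalized values, both called. No other list was called. The NLRP3 list had 15 of 20 members lower (median -0.16, camera adjusted p = 0.299), but 3 members passed when adjusted over the list alone, Nlrp3, P2rx7 (-1.42 ± 0.35) and Panx1 (-1.18 ± 0.31, 1 of 2 knockout arrays above background). Alternative activation had 15 of 21 members higher (median 0.18, camera adjusted p = 0.0688), and 3 passed when adjusted over the list alone, Retnla (2.25 ± 0.34), Folr2 (2.25 ± 0.35) and Irf4 (1.39 ± 0.33, 1 of 2 wild-type arrays above background). Hypoxia and glycolysis genes had 23 of 29 higher (median 0.13, camera adjusted p = 0.0530), with the lactate exporter Slc16a3 at 1.15 ± 0.31, Egln3 at 0.66 ± 0.21 and the heme oxygenase Hmox1 at 0.96 ± 0.34. Other probes of Slc16a3 gave 0.06 and -0.16.

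**Figure D2:**
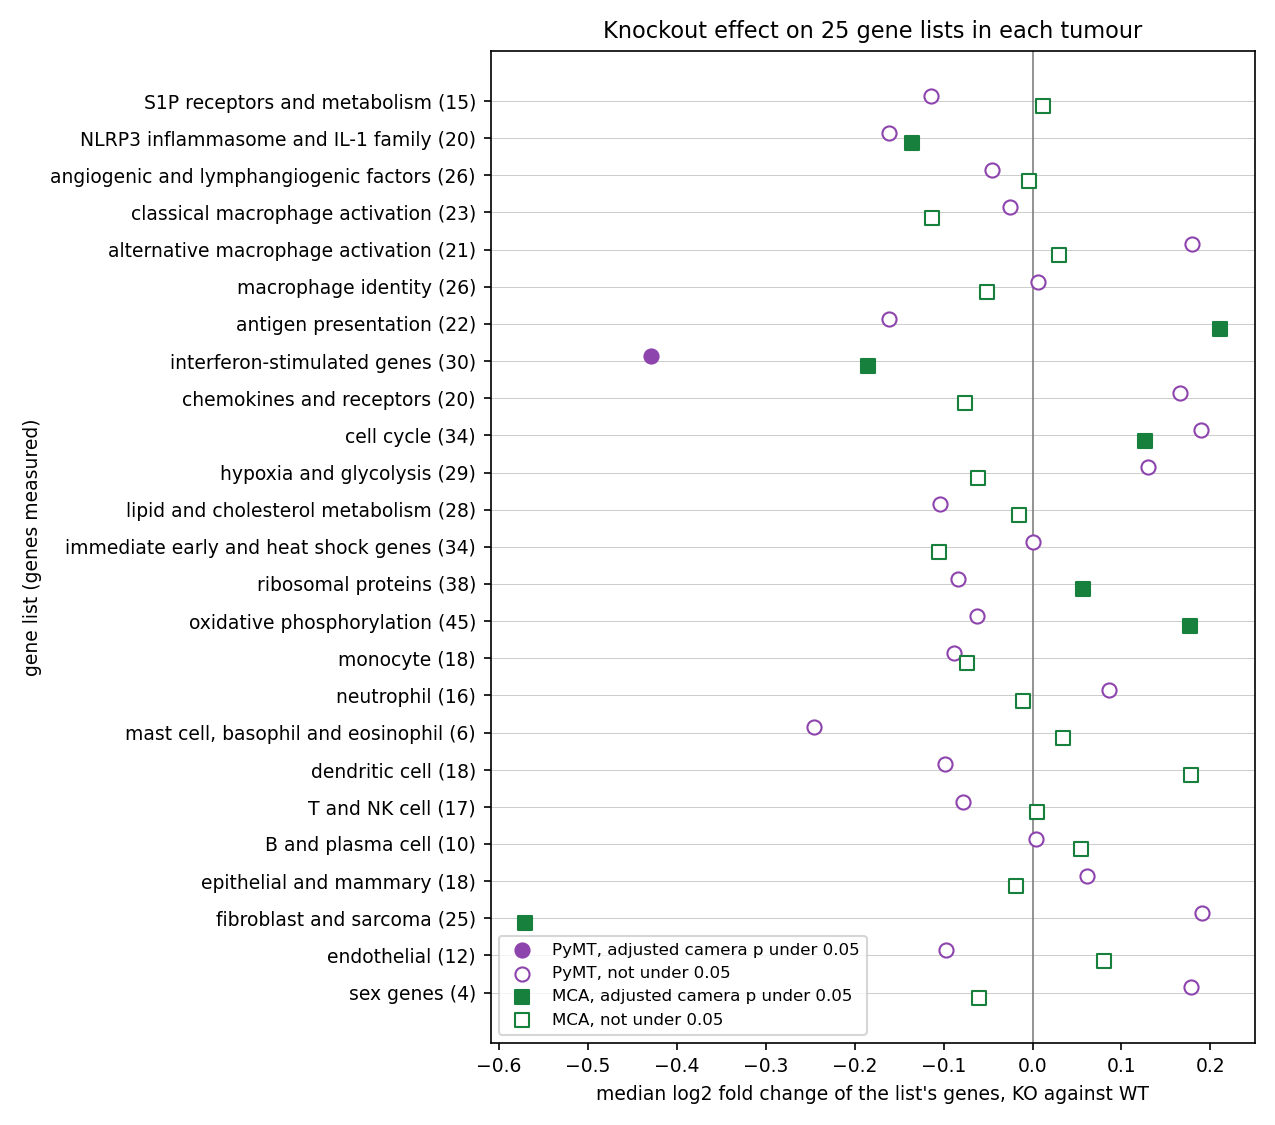
Median log2 fold change of the measured genes of each of 25 lists in PyMT (circles) and MCA (squares), S1PR1 knockout against wild type. Filled symbols mark an adjusted camera p under 0.05, with interferon-stimulated genes at -0.43 in PyMT and fibroblast markers at -0.57 in MCA lowest.

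In MCA tumours Tnfsf9 (8.22 against 9.22, -1.01 ± 0.17), Arhgap22 (-0.90 ± 0.17), Abcd3 (-0.96 ± 0.21), the deubiquitinase Josd1 (-0.86 ± 0.19) and the olfactory receptor gene Olfr222 (-1.01 ± 0.18) were lowest by p in knockout (2 arrays per genotype). Higher were Rufy4 (1.31 ± 0.18), the mitochondrial co-activator gene Ppargc1b (1.64 ± 0.25), the phospholipid transporter Abcb4 (1.77 ± 0.28), Bdh2 (2.22 ± 0.35) and the glutathione transferase Gstt1 (1.12 ± 0.19, 1 of 2 wild-type arrays above background). None passed: limma called 0 of 14103 genes, and the smallest adjusted p was 1. At its nominal level a test gives 705 genes with an unadjusted p under 0.05 by chance. The simulated arrays, with the spread of each tumour, had 301 such genes among those unchanged. In MCA there were 222 (127 higher, 95 lower). That count was 115 without KO_MCA replicate 2, 379 without WT_MCA replicate 1 and 352 without either KO_PyMT array, and it was 526 with only the MCA arrays, 522 with array weights and 525 with the spread of each tumour on its own.

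Camera called 7 lists in MCA, and in each of them 0 members passed when adjusted over the list alone. Oxidative phosphorylation genes, which encode the respiratory chain, rose, with 40 of 45 higher (median 0.18, camera adjusted p = 7.56e-06, adjusted p = 0.553 with an estimated correlation). Ndufv1, Cyc1, Cox5a and Atp5l measured 0.73 ± 0.25, 0.50 ± 0.21, 0.42 ± 0.19 and 0.45 ± 0.23. Antigen presentation genes rose, with 17 of 22 higher (median 0.21, camera adjusted p = 0.00165, adjusted p = 0.513 with an estimated correlation). The class II genes H2-Eb1, H2-Aa and H2-DMb2 and their chaperone gene Cd74 measured 0.57 ± 0.20, 0.44 ± 0.21, 0.36 ± 0.18 and 0.38 ± 0.19. The NLRP3 list fell, with 17 of 20 lower (median -0.14, camera adjusted p = 0.00252, adjusted p = 0.448 with an estimated correlation), among them Il1a (-0.56 ± 0.20) and Il1r2 (-0.80 ± 0.31) beside Nlrp3 and Il1b. Without KO_MCA replicate 1 the oxidative phosphorylation median was 0.09 (camera adjusted p = 0.221) and the antigen presentation median 0.13 (0.182), and both calls ended. The antigen presentation call also ended without WT_MCA replicate 2 (0.11, camera adjusted p = 0.246), and the oxidative phosphorylation median was then 0.10, and 0.27 without KO_MCA replicate 2 or WT_MCA replicate 1. The NLRP3 call ended without KO_MCA replicate 2 (-0.21, camera adjusted p = 0.0561), and the median was -0.24 without KO_MCA replicate 1 and -0.26 without WT_MCA replicate 2. Without background correction the medians were -0.07 for the NLRP3 list and 0.13 for antigen presentation, still called.

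Fibroblast and sarcoma markers were lower in MCA knockout, with 24 of 25 members lower (median -0.57, camera adjusted p = 0.00191, adjusted p = 0.561 with an estimated correlation). Thy1, Timp3, Fbn1 and Col5a1 measured -0.94 ± 0.64, -1.13 ± 0.79, -0.80 ± 0.58 and -0.77 ± 0.62. The wild-type arrays stood apart from each other: the mean level of the list was 6.59 on WT_MCA replicate 2 and 4.67 on WT_MCA replicate 1, against 5.08 and 5.20 on the knockout arrays. Without WT_MCA replicate 2 the median turned to 0.42 (camera adjusted p = 5.77e-07). It was -1.72 without WT_MCA replicate 1 and -0.39 without KO_MCA replicate 1, where the call ended (camera adjusted p = 0.0974). Among genes above background on all 8 arrays it was -0.49 (camera adjusted p = 0.102), and without background correction -0.36, still called. Interferon-stimulated genes had 25 of 30 members lower (median -0.18, camera adjusted p = 0.0325, adjusted p = 0.596 with an estimated correlation), with Dhx58 at -0.48 ± 0.30, Rsad2 at -0.44 ± 0.32, Isg15 at -0.44 ± 0.36 and Gbp2 at 0.68 ± 0.43. Here too the wild-type arrays differed, with mean levels of 7.60 on WT_MCA replicate 1 and 6.73 on WT_MCA replicate 2 against 7.11 and 6.88. The median turned to 0.23 without WT_MCA replicate 1 (camera adjusted p = 0.00946), and was -0.67 without WT_MCA replicate 2 and -0.13 without KO_MCA replicate 2 (camera adjusted p = 0.712). Without background correction it was -0.11, still called.

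Cell cycle genes in MCA had 25 of 34 higher (median 0.13, camera adjusted p = 0.0290, adjusted p = 0.561 with an estimated correlation), with Mcm6 at 0.33 ± 0.18, Tpx2 at 0.52 ± 0.28, Birc5 at 0.69 ± 0.39 and Cdt1 at 0.34 ± 0.19. The median turned to -0.13 without WT_MCA replicate 2 (camera adjusted p = 0.713). It was 0.08 without KO_MCA replicate 1 (camera adjusted p = 0.315), 0.25 without KO_MCA replicate 2 and 0.39 without WT_MCA replicate 1. Ribosomal protein genes had 29 of 38 higher and 8 lower (median 0.06, camera adjusted p = 0.0325, adjusted p = 0.448 with an estimated correlation), with Rps16 at 0.28 ± 0.18, Rpl34 at 0.24 ± 0.19, Rps7 at 0.24 ± 0.20 and Rps10 at 0.19 ± 0.18. That call ended without KO_MCA replicate 1 (0.08, camera adjusted p = 0.220), KO_MCA replicate 2 (0.08, 0.0561) or WT_MCA replicate 1 (0.06, 0.388), and the median was 0.11 without WT_MCA replicate 2. Without either KO_PyMT replicate, which enter only through the spread, camera adjusted p was 0.0518 for the ribosomal list and 0.0575 for the interferon list. Under median scaling all 3 lists lost their calls, at -0.21 for interferon-stimulated genes, 0.12 for the cell cycle and 0.08 for ribosomal proteins (camera adjusted p = 0.0659). The interferon and ribosomal calls also ended with each tumour normalized on its own (-0.18 and 0.06, camera adjusted p = 0.0608) and with only the MCA arrays (-0.18 and 0.06, 0.0767 and 0.0632). The interferon call ended without a detection filter (-0.16, camera adjusted p = 0.0776), and the ribosomal call with a stricter one (0.06, 0.0538) and among genes above background on all 8 arrays (0.07, 0.0589). Still called, the cell cycle median was 0.05 without background correction and 0.23 with the repeat array in place of its partner, and the ribosomal median 0.10 by the mean of probes.

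**Figure D3:**
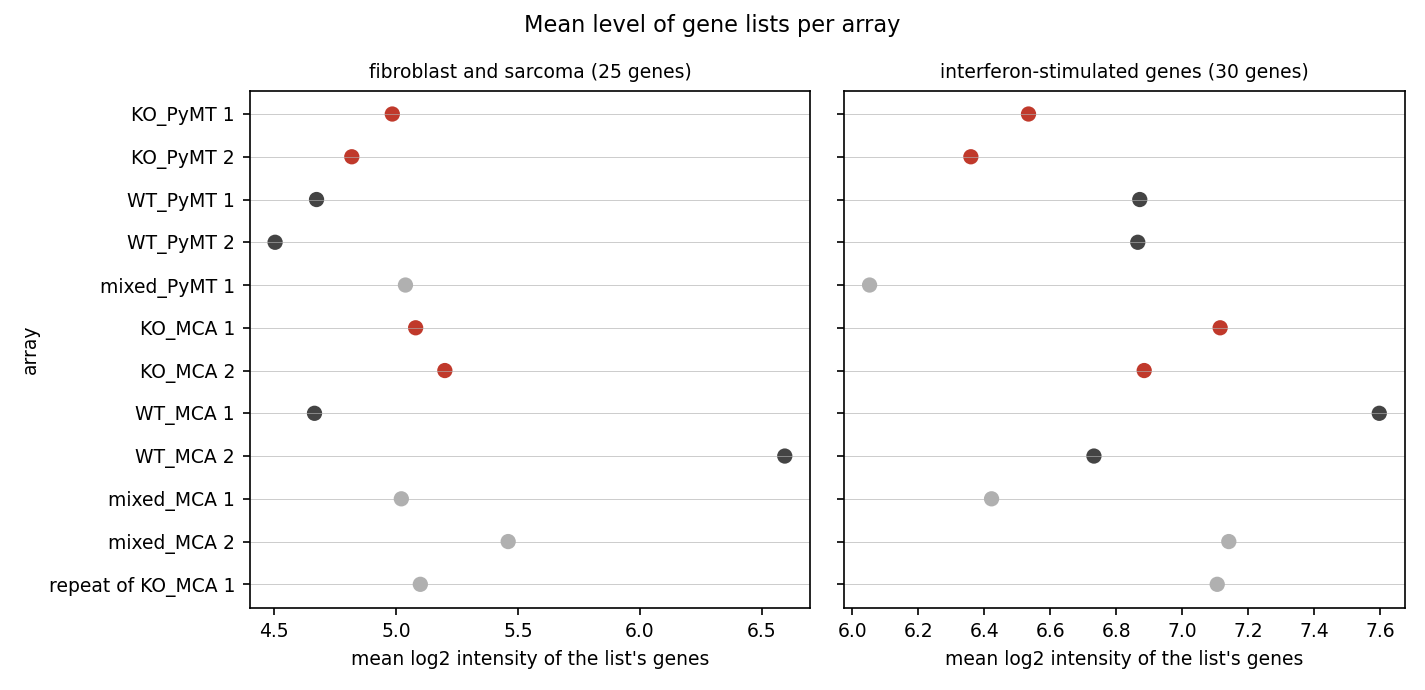
Mean log2 intensity of the fibroblast and sarcoma markers (left) and the interferon-stimulated genes (right) on all 12 arrays, knockout in red, wild type in dark grey, mixed and repeat arrays in light grey. WT_MCA replicate 2 was highest for the fibroblast markers at 6.59, and WT_MCA replicate 1 for the interferon-stimulated genes at 7.60.

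Whether the knockout acted alike in both tumours was tested by the difference of the effects, PyMT minus MCA. R3hcc1l (2.35 ± 0.26), the p53 target Phlda3, Josd1 (1.92 ± 0.27), Txnl2 and Adamtsl5 (2.57 ± 0.37, 1 of 2 arrays above background in each MCA group) had the smallest p and did not pass (limma adjusted p = 0.532). No exact difference is given for Phlda3, below background in WT_PyMT and KO_MCA, or for Txnl2, below background in every group but KO_PyMT. limma called 0 genes, and 812 had an unadjusted p under 0.05 (336 higher, 476 lower), a count of 1623 without KO_PyMT replicate 1, 1522 without KO_PyMT replicate 2 and 507 without KO_MCA replicate 2. Without KO_PyMT replicate 2 it called 1, the transcription factor Tfap2c (limma adjusted p = 0.0120), named after its values were seen, which were 9.54 on KO_PyMT replicate 1 and at most 4.78 on the other group arrays. Across genes, which are not independent replicates, the effects in PyMT and MCA correlated with Pearson's r of 0.036 and Spearman's rho of 0.030, and 50.6% had the same sign. Of 18 signed splits of the arrays, 3 gave an r as high, the real one included, and the highest other was 0.0586. At an unadjusted p under 0.05 in both tumours there were 46 genes, 13 higher in both, 16 lower in both and 17 opposite. Independent lists give 6.07 higher in both, 5.77 lower in both and 12.3 opposite. Both tests share 1 estimate of the spread per gene, which can raise all of these counts but does not of itself favour the same direction. Whether the larger excess in the same direction goes beyond chance was not tested. These counts therefore do not decide on a shared response.

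Camera called 6 lists as differing between tumours, with 0 members passing in each when adjusted over the list alone. Antigen presentation genes differed by a median of -0.44 (20 of 22 lower, camera adjusted p = 0.00150, adjusted p = 0.336 with an estimated correlation), with H2-Ob at -1.94 ± 0.80 (1 of 2 KO_PyMT arrays above background), H2-DMb1 at -0.72 ± 0.34, H2-Eb1 at -0.60 ± 0.28 and H2-DMa at -0.48 ± 0.24. This call held without each array in turn, at -0.36 to -0.52, while the median was -0.27 without background correction and -0.25 from the authors' normalized values, still called. Oxidative phosphorylation genes differed by -0.27 (36 of 45 lower, camera adjusted p = 0.00446, adjusted p = 0.683 with an estimated correlation), with Uqcrc2 at -1.33 ± 0.44 and Atp5k at -0.65 ± 0.31. Ribosomal protein genes differed by -0.19 (30 of 38 lower, camera adjusted p = 0.0116, adjusted p = 0.293 with an estimated correlation), with Rps13 at -0.88 ± 0.24 and Rpl22 at -1.47 ± 0.53 (1 of 2 KO_PyMT arrays above background). In the other direction, hypoxia and glycolysis genes differed by 0.21 (27 of 29 higher, camera adjusted p = 0.00446, adjusted p = 0.293 with an estimated correlation), with Slc16a3 at 1.20 ± 0.43, Egln3 at 0.76 ± 0.30 and Car9 at 1.36 ± 0.57. Chemokines and receptors differed by 0.25 (16 of 20 higher, camera adjusted p = 0.0171, adjusted p = 0.336 with an estimated correlation), with Cxcl1 at 1.00 ± 0.33, Pf4 at 1.58 ± 0.58 and Ccl7 at 0.68 ± 0.33. Fibroblast markers differed by 0.61 (22 of 25 higher, camera adjusted p = 0.00446, adjusted p = 0.777 with an estimated correlation), with Timp3 at 2.20 ± 1.12.

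Leaving out single arrays ended 5 of these 6 calls, in several cases with a median as large as in the full fit. Without KO_PyMT replicate 1 the medians were 0.25 for hypoxia, -0.28 for oxidative phosphorylation, 0.47 for fibroblast markers, -0.17 for ribosomal proteins and 0.29 for chemokines, with camera adjusted p of 0.0658 to 0.101. Without WT_PyMT replicate 2 hypoxia (0.22), oxidative phosphorylation (-0.26), fibroblast markers (0.57) and ribosomal proteins (-0.19) were no longer called. Without KO_MCA replicate 1 this held for oxidative phosphorylation (-0.23), ribosomal proteins (-0.10) and chemokines (0.25). Without WT_MCA replicate 2 the fibroblast median turned to -0.01, oxidative phosphorylation (-0.19) and chemokines (0.20) lost the call, and the hypoxia median was 0.37. Chemokines and ribosomal proteins also lost it without KO_PyMT replicate 2 (0.29 and -0.17) or WT_PyMT replicate 1 (0.23 and -0.19), where the hypoxia median was 0.33. Without WT_MCA replicate 1 ribosomal proteins (-0.17) lost the call, and the medians were 2.04 for fibroblast markers and 0.60 for chemokines. Median scaling ended the calls of ribosomal proteins (-0.12, camera adjusted p = 0.193) and oxidative phosphorylation (-0.20, 0.0963), a stricter detection filter that of ribosomal proteins (-0.19, 0.0554), and genes above background on all 8 arrays that of fibroblast markers (1.25, 0.182). Still called, the medians without background correction were 0.15 for chemokines and -0.18 for oxidative phosphorylation, and that of hypoxia under median scaling 0.33.

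The macrophage pools sorted from PyMT and MCA tumours differed in 23 called genes, 21 higher and 2 lower in PyMT. Whether such genes as Wfdc18 and Csn3 were expressed by macrophages or by other cells in the pools was not tested. H2-M2, a nonclassical histocompatibility gene, was 10.06 against 4.61 (43.6-fold, limma adjusted p = 1.03e-04, 3 of 4 MCA arrays above background). Mmp12, the macrophage elastase, was 8.80 against 6.35 (2.45 ± 0.20, 5.48-fold), and Ifnb1, which encodes interferon-β, was 8.93 against 5.88 (3.05 ± 0.38, 8.27-fold, limma adjusted p = 0.0333). On the mixed arrays, outside this fit, Mmp12 was 7.70 for PyMT and 8.51 and 6.95 for MCA, and Ifnb1 8.35, 8.22 and 4.57. So 1 MCA mixed array lay near or above the PyMT one for both genes, while H2-M2 was 8.42, 4.83 and 4.22. Wfdc18, of the whey acidic protein family, was below background in MCA and at least 4.88-fold higher in PyMT. The semaphorin Sema4b (2.30 ± 0.23), the Wnt receptor Fzd7 (2.04 ± 0.26) and the olfactory receptor gene Olfr111 (3.95 ± 0.39, 3 of 4 MCA arrays above background) were also higher. Daam2 (3.75 ± 0.28, 3 of 4 MCA arrays above background) and the calcium sensor Stim1 (3.43 ± 0.30) were higher by their brightest probe, while their other probes gave -0.18 and -0.10. Xist was at least 30.2-fold higher in PyMT and the Y-linked Eif2s3y lower (-1.81 ± 0.18, 1 of 4 PyMT arrays above background), as the labelled sexes differ. The coatomer gene Copz2 was lower (-1.36 ± 0.16, 1 of 4 PyMT arrays above background).

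**Figure D4:**
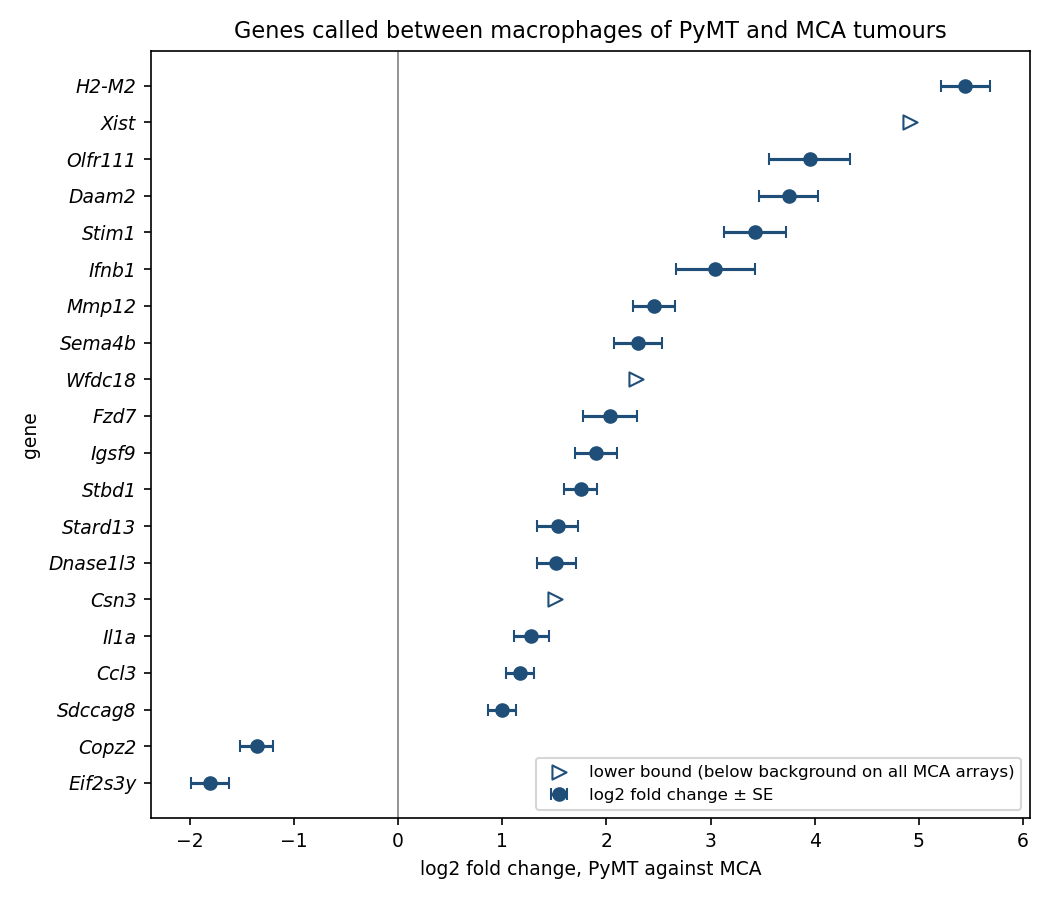
Log2 fold change with SE (circles), or its lower bound where a gene was below background on all MCA arrays (open triangles), of the 20 named genes called between macrophages of PyMT and MCA tumours, 4 arrays each. Of these, 18 were higher in PyMT, among them H2-M2 at 5.45 and Xist at 4.92 or more, and Copz2 and Eif2s3y were lower.

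The remaining called genes, named after their values were seen, included the inflammatory mediators Ccl3 (1.17 ± 0.14, limma adjusted p = 0.0260) and Il1a (1.28 ± 0.17, limma adjusted p = 0.0395), the milk protein gene Csn3 (at least 2.85-fold), and Igsf9, Stbd1, Stard13, Dnase1l3 and Sdccag8 at 1.90, 1.76, 1.53, 1.52 and 1.00. A further 3 carry only clone or predicted names. At an unadjusted p under 0.05 there were 2121 genes (922 higher, 1199 lower), and 1403 without KO_MCA replicate 1. Within 1 BeadChip, KO_PyMT can be set only against the repeat array of KO_MCA replicate 1, an arm of 1 array without a spread of its own, so its limma calls (0, with 593 genes at an unadjusted p under 0.05) say nothing about the BeadChip. The 12 genes named by rule had the same direction there, with H2-M2 at 5.53, Mmp12 at 2.80, Ifnb1 at 2.60, Eif2s3y at -0.94 and Copz2 at -1.86. With the difference of the repeat array from its partner added to the MCA arrays, 22 of the 23 genes stayed called. limma then called 189 genes (90 higher, 99 lower), with H2-M2 at 5.34, Mmp12 at 2.53 and Ifnb1 at 2.32. Under median scaling the calls were 19 higher and 59 lower, and the median of all genes was -0.13. The split of directions therefore depends on the scaling and on that addition. Leaving out single arrays gave 14 calls without WT_PyMT replicate 1 and 8, 8 and 9 without KO_MCA replicate 1, KO_MCA replicate 2 and WT_MCA replicate 2. Ifnb1 lost its call without KO_PyMT replicate 1 or 2 or any of the 4 MCA arrays, at 2.89 to 3.22, and Fzd7 without any array but KO_PyMT replicate 1, at 1.87 to 2.18. Copz2 lost it without any array but WT_PyMT replicate 2, at -1.27 to -1.42. Olfr111 lost it without KO_MCA replicate 1 (3.81) or 2 (3.77), Sema4b without KO_MCA replicate 1 (2.21) or 2 (2.21) or WT_MCA replicate 2 (2.27), and Eif2s3y without WT_PyMT replicate 1 (-1.74), KO_MCA replicate 2 (-1.76) or WT_MCA replicate 2 (-1.73).

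Processing changed the size or the call of several of these genes. Without background correction H2-M2 measured 3.59, Olfr111 2.22, Daam2 2.38, Fzd7 1.07, Eif2s3y -0.64 and Copz2 -0.45, all still called, since an uncorrected background shrinks folds. By the mean of probes Daam2 was 1.78, Stim1 1.67 and Eif2s3y -1.07, still called, while Fzd7 at 1.15 and Copz2 at -0.62 were not (limma adjusted p = 0.0524 and 0.0682). Ifnb1 was not called without background correction (2.11), from the authors' normalized values (2.08), without a detection filter (3.05) or with the mixed arrays added (3.05), with limma adjusted p of 0.0616 to 0.0971. Without a detection filter Fzd7 (2.04), Olfr111 (3.95) and Sema4b (2.30) also lost the call, as did Fzd7 under median scaling (1.79), Eif2s3y with the repeat array in place of its partner (-1.72) and Copz2 among genes above background on all 8 arrays (-0.16).

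Among the lists, oxidative phosphorylation genes were lower in PyMT macrophages, 44 of 45 (median -0.33, camera adjusted p = 5.81e-10, adjusted p = 0.356 with an estimated correlation), with 8 passing when adjusted over the list alone, such as Atp5o (-0.74 ± 0.14), Atp5a1 (-0.60 ± 0.13) and Sdha (-1.08 ± 0.25, 3 of 4 PyMT arrays above background, another probe 0.30). Cell cycle genes fell, 25 of 34 (median -0.28, camera adjusted p = 1.58e-04, adjusted p = 0.418 with an estimated correlation), with 9 passing when adjusted over the list alone, among them Mcm6 (-0.71 ± 0.13), Mcm7 (-1.08 ± 0.24, 3 of 4 PyMT arrays above background), Plk1 (-0.88 ± 0.20) and Cdk1, at least 1.94-fold lower. Interferon-stimulated genes fell, 28 of 30 (median -0.39, camera adjusted p = 1.58e-04, adjusted p = 0.677 with an estimated correlation), with 2 passing when adjusted over the list alone, Isg20 (-1.32 ± 0.22, 2 of 4 PyMT arrays above background) and Gbp2 (-1.46 ± 0.35), although Ifnb1 was higher. Ribosomal protein genes fell, 31 of 38 (median -0.19, camera adjusted p = 9.15e-04, adjusted p = 0.532 with an estimated correlation), with 0 passing when adjusted over the list alone, Rps10 at -0.69 ± 0.16 and Rps7 at -0.72 ± 0.19, but Rps18 at 0.80 ± 0.21. Median scaling gave larger drops of these lists, to -0.60, -0.58, -0.61 and -0.38, and the medians within 1 BeadChip, against a single array, were -0.53, -0.57, -0.62 and -0.35. Without background correction the interferon median was -0.19. Without WT_MCA replicate 2 the medians were -0.54 for the cell cycle and -0.61 for interferon-stimulated genes, and the cell cycle median was -0.46 without KO_PyMT replicate 2 and -0.47 without WT_PyMT replicate 2.

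Markers of other cell types also differed, and whether their signal came from macrophages or from other cells in the pools was not tested. Epithelial and mammary markers were higher in PyMT for 18 of 18 members (median 0.30, camera adjusted p = 9.95e-05, adjusted p = 0.119 with an estimated correlation), with the cadherin Cdh1 at 1.34 ± 0.37, Mfge8 at 0.76 ± 0.36 and 1 passing when adjusted over the list alone, Csn3. Dendritic cell markers were higher for 16 of 18 (median 0.29, camera adjusted p = 9.15e-04, adjusted p = 0.126 with an estimated correlation), with 5 passing when adjusted over the list alone, among them Siglech (1.73 ± 0.28), Batf3 (1.24 ± 0.22) and Itgax (1.31 ± 0.24). T and NK cell markers were higher for 12 of 17 (median 0.15, camera adjusted p = 0.0238, adjusted p = 0.290 with an estimated correlation), with 3 passing when adjusted over the list alone, Il7r (1.94 ± 0.28), Prf1 (0.95 ± 0.14) and Cd3d, at least 1.62-fold. Fibroblast markers were lower for 19 of 25 (median -0.36, camera adjusted p = 0.00763, adjusted p = 0.677 with an estimated correlation), with Bgn at -2.29 ± 0.65, Fstl1 at -2.21 ± 0.81 (1 of 4 PyMT arrays above background), Col1a1 at least 4.94-fold and Col5a1 at least 3.39-fold lower, and 0 passing when adjusted over the list alone. Alternative activation genes rose, 15 of 21 (median 0.36, camera adjusted p = 0.0370, adjusted p = 0.532 with an estimated correlation), with 4 passing when adjusted over the list alone, among them Retnla, below background in MCA and at least 8.28-fold higher, Ccl24 (0.83 ± 0.22, 1 of 4 MCA arrays above background) and Klf4 (-0.79 ± 0.23).

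Within 1 BeadChip, against a single array, the medians were 0.17 for epithelial, 0.11 for dendritic, 0.08 for T and NK cell and -0.14 for fibroblast markers, and calls are not compared there. The fibroblast call ended without WT_PyMT replicate 2 (-0.16) or WT_MCA replicate 2 (-0.04), and the median was -0.73 without KO_PyMT replicate 1 or WT_MCA replicate 1 and -0.59 without WT_PyMT replicate 1. The alternative activation call ended without KO_PyMT replicate 2 (0.08), KO_MCA replicate 1 (0.25) or WT_MCA replicate 1 (0.31) and among genes above background on all 8 arrays (0.00), and the median was 0.22 without WT_PyMT replicate 2. The T and NK cell call ended without WT_PyMT replicate 1 (0.16) or WT_MCA replicate 2 (0.13), and that median was 0.09 without KO_PyMT replicate 1. The dendritic median was 0.14 without WT_PyMT replicate 1. Median scaling gave fibroblast -0.59 (no longer called), dendritic 0.16 and T and NK cell 0.08. Adding the repeat difference between BeadChips to the MCA arrays ended the epithelial (0.15), T and NK cell (0.08) and alternative activation (0.30) calls. Their camera adjusted p were 0.0628, 0.119 and 0.0507. The epithelial median was 0.10 from the authors' normalized values and without background correction, the dendritic 0.11 and the fibroblast -0.17 without it, all still called. Without background correction T and NK cell (0.04) and alternative activation (0.14) lost theirs, as did alternative activation without a detection filter (0.13) or with a stricter one (0.04), and fibroblast markers among genes above background on all 8 arrays (-0.18).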

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

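The tests of spread, background, genotype split, fibroblast markers, Abcd3 probes and neighbouring genes were chosen only after the results were seen, while the counts of other splits of the arrays were chosen before.

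In 6 lists the effect of the knockout differed between tumours by the camera test of the difference itself. Antigen presentation genes differed by -0.44 (PyMT -0.16, MCA 0.21) and oxidative phosphorylation genes by -0.27 (-0.06 and 0.18). Fibroblast and sarcoma markers differed by 0.61 (0.19 and -0.57) and hypoxia and glycolysis genes by 0.21 (0.13 and -0.06). Ribosomal protein genes differed by -0.19 (-0.08 and 0.06) and chemokines and receptors by 0.25 (0.17 and -0.08). None of the 6 was called with an estimated correlation between genes, with adjusted p of 0.293 to 0.777. Leaving out single arrays ended each of these calls but that of antigen presentation. The fibroblast difference turned to -0.013 without WT_MCA replicate 2. Tumour, sex and BeadChip cannot be told apart in these differences, since the design confounds them.

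At an unadjusted p under 0.05 there were 1531 genes in PyMT and 222 in MCA, a ratio of 6.90. With each tumour fitted on its own 4 arrays the counts were 941 and 526 and the ratio fell to 1.79, so a shared estimate of the spread, with replicates further apart in PyMT, may account for much of it. Loss of faint genes on single arrays is argued against, since among genes above background on all 8 arrays the ratio was 8.85. A larger effect of the knockout in PyMT stays open: the genotype split of the 4 PyMT arrays gave 941 genes and the highest other split 693, but 3 splits are too few for a share under 0.05. In MCA the genotype split gave 526 genes and the other splits 912 and 611, so splits that mix genotypes gave counts of this size too.

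Fibroblast and sarcoma markers were lower in MCA knockout, and 88% of the 25 measured markers were highest on WT_MCA replicate 2, where chance gives 25%, while monocyte markers moved there too, with 55.6% of 18 highest on that array. Both wild-type arrays lay above both knockout arrays in 4% of the fibroblast and sarcoma markers, where chance gives 16.7% for independent markers. These markers moved together by array, so this cannot decide on an effect of the knockout. With a mean level of 4.67 on WT_MCA replicate 1, below both knockout arrays, the lower level in knockout rests on WT_MCA replicate 2. A candidate explanation is sarcoma or stromal cells in that pool. The sort for high CD11b is meant to remove them, and how fully it did was not tested. On that array Sparc was 9.69, Bgn 9.55, Fstl1 9.04 and Col1a1 8.91, where the other 3 MCA group arrays had 5.94 to 7.04, 6.32 to 7.67, 4.59 to 6.49 and 4.84 to 6.34. Of the 25 markers 15 were above background on all of those 3 arrays and 1, Thy1, is also in another list.

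Abcd3 was lower in the knockout of both tumours by -1.50 ± 0.24 on its reported probe. Less Abcd3 transcript of every form is argued against, since the next brightest probe, above background on all 8 arrays, gave -0.14 (-0.51 to 0.22). Abcd3 lies on the same chromosome as S1pr1, so DNA of another strain flanking the knocked-out gene may alter the reported probe's target. Among the 40 measured neighbours of S1pr1, 5 had an unadjusted p under 0.05, and 7.05% of all such windows had as many, so that explanation stays open. The remaining probes, near background, gave 0.09 and -0.24.

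The 8 arrays split into 4 and 4 in 35 ways, of which 34, the real one included, could be fitted, since the split that matches the other factor of the model cannot. For knockout against wild type over both tumours limma called 0 genes, as did all 34 splits (highest other 0), and a count of 0 cannot bear on chance. At an unadjusted p under 0.05 the real split gave 722 genes, 9 of 34 splits gave as many, and the highest other gave 932. Of lists it called 4, 12 of 34 splits called as many, and the highest other called 8, so chance cannot be excluded for the 722 genes or the 4 lists. For PyMT against MCA limma called 23 genes in 1 of 34 splits, the real one, and at most 0 in any other. That is the smallest share that 34 splits allow. The other splits leave the tumour difference in their spread, which can lower their counts. This argues against chance without excluding it, and the real split is also that of sex and BeadChip. With the difference of the repeat array from its partner added to the MCA arrays limma called 189 genes, 22 of the 23 among them. This argues against the BeadChip as the whole cause of those 22, while sex and tumour cannot be told apart. Whether sorting or amplification also went with tumour is not given in the sources used here. The repeat array, of the same sample as its partner, may not reflect such steps. The difference of the repeat array from its partner comes from 1 pair of arrays and its error is not carried into the test. The 9 lists called for PyMT against MCA were matched in 3 of 34 splits (highest other 9), so for the lists chance cannot be excluded.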

How the results depend on the processing

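The fits with normexp without the deposited p, with the spread of each tumour on its own and among genes above background on all 8 arrays were chosen after seeing the data. Precision is limited by 2 arrays per group and by signal near background, and leaving out 1 array assumes that the lone array left varies like the other groups. Where no reason is given, the cause was not tested.

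For knockout against wild type in PyMT, limma called 7 genes without background correction, 6 from the authors' normalized values, 4 without a detection filter and 10 with mixed arrays added, against 0, and 0 to 108 with 1 array left out. Over both tumours it called 2 without background correction and 2 from the authors' values. The difference between tumours had 0 to 1 with 1 array left out. For PyMT against MCA, against 23, it called 78 under median scaling, 47 without background correction, 44 from the authors' values and 46 with mixed arrays added. It called 40 with a trended robust prior, 40 with normexp without the deposited p and 14 among genes above background on all 8 arrays. With the repeat difference added to the MCA arrays it called 189 (90 higher and 99 lower, 22 of the 23 among them). With 1 array left out it called 8 to 24. Within 1 BeadChip there are 3 arrays, 1 of them the whole MCA arm, so no call can be weighed.

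Of the lists, camera called 1 in PyMT, and 4 under median scaling, 4 without background correction, 2 with each tumour normalized on its own, 4 from the authors' values, 4 without a filter, 4 with normexp without the deposited p, 2 from only PyMT arrays, 0 among genes above background on all 8 arrays and 0 to 2 with 1 array left out. In MCA it called 7, 4 under median scaling and 2 to 9 with 1 array left out. Over both tumours it called 4, 2 without a filter, 1 among genes above background on all 8 arrays and 1 to 6 with 1 array left out. For the difference it called 6, and 1 to 8 with 1 array left out, and for PyMT against MCA 9, and 8 to 10. With an estimated correlation camera called 0 lists in PyMT, 0 in MCA, 0 over both, 0 for the difference and 0 for PyMT against MCA. Fry called 0, 0, 0, 1 and 6.

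With 1 array left out, 4 medians turned: interferon-stimulated genes in MCA to 0.23 (range -0.67 to 0.23), the cell cycle in MCA to -0.13 (-0.13 to 0.39), and fibroblast markers to 0.42 in MCA (-1.72 to 0.42) and -0.013 for the difference (-0.013 to 2.04). Pearson's r between the effects in PyMT and MCA was -0.017 to 0.078. Counts at an unadjusted p under 0.05 stayed within a factor of 1.5 in 100 comparisons and left it in 25. In MCA the count was 522 with array weights, 352 without KO_PyMT replicate 1 or 2, 379 without WT_MCA replicate 1 and 115 without KO_MCA replicate 2. For the difference it was 1623 and 1522 without KO_PyMT replicate 1 or 2 and 507 without KO_MCA replicate 2, and for PyMT against MCA 1403 without KO_MCA replicate 1. Values of named genes kept direction and side of the threshold in 1283 comparisons, gained a call in 34 and lost one in 52. Only genes named for PyMT against MCA had a call in the main fit to lose, so all 52 losses were among them. Most of the 1283 were of genes that stayed uncalled. The losses include those of the fit within 1 BeadChip, where no call can be weighed. Called lists kept direction and call in 557 comparisons, lost the call in 95 and turned in 4.

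With a replicate block camera called 3 lists in PyMT, limma called 0 genes in each knockout comparison and in their difference, with 1530 in PyMT, 212 in MCA, 655 over both and 850 for the difference at an unadjusted p under 0.05, and the ribosomal call in MCA ended. Whether replicate numbers pair the samples was checked by r of -0.005 in PyMT and 0.079 in MCA.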

Other observations

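All tests in this part were chosen before the data were examined.

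Several lists had no call for the knockout, and of the genes named from them here 1, Lpl, passed when adjusted over the list alone. In S1P receptors and metabolism the medians were -0.11 in PyMT, 0.01 in MCA and -0.09 over both tumours (camera adjusted p = 0.845, 0.354 and 0.633), with the receptor S1pr2 at -0.46 ± 0.20 over both. In lipid and cholesterol metabolism they were -0.10, -0.01 and -0.12 (0.883, 0.426 and 0.812), with the lipase Lpl at 2.11 ± 0.42 in MCA and the scavenger receptor Cd36 at 1.23 ± 0.25 in PyMT. Angiogenic and lymphangiogenic factors measured -0.05, 0.00 and 0.06 (0.845, 0.699 and 0.820), with Nrp2 at 1.57 ± 0.51 over both. Classical activation measured -0.03, -0.11 and -0.05 (0.845, 0.0714 and 0.458), with the co-stimulator Cd40 at -0.54 ± 0.15, and macrophage identity 0.01, -0.05 and 0.01 (0.845, 0.595 and 0.812), with Itgam, which encodes CD11b, at -0.63 ± 0.18. Immediate early and heat shock genes measured 0.00, -0.11 and -0.05 (0.883, 0.175 and 0.812).

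Marker lists without a call for the knockout, in PyMT, MCA and both tumours, were these. Monocyte markers measured -0.09, -0.07 and -0.11, but the MCA wild-type arrays stood apart, with mean levels of 5.79 on WT_MCA replicate 1 and 6.87 on WT_MCA replicate 2 against 6.22 on both knockout arrays. Neutrophil markers measured 0.09, -0.01 and 0.00, and mast cell, basophil and eosinophil markers -0.25, 0.03 and -0.07. Dendritic cell markers measured -0.10, 0.18 and -0.03, with Dpp4 at least 3.85-fold lower in PyMT, and T and NK cell markers -0.08, 0.00 and 0.00, with Cd2 at 2.11 ± 0.33 in PyMT (1 of 2 wild-type arrays above background). B and plasma cell markers measured 0.00, 0.05 and 0.06, epithelial and mammary markers 0.06, -0.02 and 0.03, endothelial markers -0.10, 0.08 and 0.02, and sex genes 0.18, -0.06 and 0.00. The highest camera adjusted p among these lists was 0.974 and the lowest 0.30. Lists whose median, mean and test differed in sign numbered 5 in PyMT, 3 in MCA, 3 over both, 8 for the difference and 6 for PyMT against MCA, and 0 of them were called.

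Between PyMT and MCA macrophages the early response genes Egr3 (1.96 ± 0.31), Ppp1r15a (1.14 ± 0.21) and Egr1 (0.70 ± 0.18) passed when adjusted over the list alone, with a list median of 0.08 (camera adjusted p = 0.0876). So did Gpnmb (2.76 ± 0.51), Itgam (-0.85 ± 0.18) and the protease Ctsd (0.64 ± 0.15) among macrophage identity genes, Thbs1 (-1.59 ± 0.31) and Mmp13 (0.70 ± 0.16) among angiogenic factors, and Lcn2 (1.17 ± 0.17, 1 of 4 MCA arrays above background), Ltf (0.84 ± 0.19, 3 of 4) and Mmp9 (-2.74 ± 0.64) among neutrophil markers. The cytokine gene Tnf measured 1.04 ± 0.20.

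The mixed arrays, which the labels put in no genotype, had Nlrp3 at 9.76 for PyMT and 9.92 and 9.78 for MCA, and Il1b at 10.07, 10.77 and 10.20. Tnfsf9 was 8.27, 8.92 and 7.92, Ifnb1 8.35, 8.22 and 4.57, and Mmp12 7.70, 8.51 and 6.95 on the same arrays. T and NK cell markers averaged 5.67 on the PyMT mixed array. The repeat array of KO_MCA replicate 1 had Nlrp3 at 9.42, Tnfsf9 at 8.33 and Il1b at 10.15.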
